A study of Homo sapiens with 16 samples.

How the data were processed

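Nascent RNA was sequenced from 16 HAP1 libraries in 8 groups of 2, as the labels name them. Per the labels' protocols, yeast RNA was added as a spike-in, RNA was fragmented with NaOH, 4-SU-labelled RNA was biotinylated with an MTSEA reagent and pulled down on streptavidin, and stranded libraries were made with 10 PCR cycles and without rRNA depletion. The submitters' processing notes list FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.7a and HOMER, with the builds GRCh38 for human and R64 for yeast, without their order or settings. Per the file headers, tags were assigned to regions with HOMER on hg38 without a strand option, so tags of overlapping and antisense genes cannot be told apart, and values of such genes are uncertain.

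The authors deposited 3 tables: 9944 gene-body regions of selected protein-coding and noncoding genes (called the mRNA table here), the 5 annotated 45S rRNA units, and 631 tRNA genes with a sum over the 5S rRNA genes. Each table has a signal column per library that the authors headed as raw counts but that, per the file headers, holds tags that HOMER scaled to a fixed library total, as tags per 10M. The 45S table carries the same deposited unit, tags per 10M. The authors also deposited a ratio column per library, its spike-in scaled value over that of the untreated library of the same number, and mean ratios per group, which were not used. Because the values were scaled and not whole, the count test planned for raw counts gave way to the fallback fixed with it, limma on log2 values. Multiplied back by the library total in the header, 91787 of 91787 mRNA values under 200 tags and 3243 of 3244 tRNA values were multiples of 0.5 tag within 0.005 of the deposited unit, since each mate of a pair counts 0.5. The tags thus recovered were used for filtering and for count tests. Library totals ran from 14083584 to 93919776.5 tags, and tags in the mRNA table from 55845.5 to 6059928.5 per library. The spread between replicates followed depth: the SD of log2 values was 0.279 in untreated cells, 0.665 after 1 h and 1.076 after 5 h of DRB.

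Genes were kept with edgeR's filterByExpr (minimum 10 tags). Values were divided by the mRNA sum times a TMM factor, so that changes are relative to typical mRNA unless another scale is named. They were tested as log2(value + 0.5) with limma's trend method. Changes of genes with few tags depend on the added 0.5 and can come out too small or too large. DRB 5 h values were divided by 0.199 and 0.222 before the 0.5 was added, so genes at 0 tags there can be fitted too low. The 14 labelled libraries entered the fit with group means, and all 16 for the comparison with cells given no 4-SU. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Class sums (mRNA, 45S, 5S and tRNA) were tested in the same fit, and their p-values were adjusted together with those of all genes tested. Whether a class passes thus also depends on how many genes changed in that comparison. Spike-in factors were taken from the deposited ratios, since the spike-in tags themselves were not used here, and gave levels as a percentage of untreated cells. Errors are SD for levels and SE for log2 changes, and a fold against a group at 0 tags is a bound from 3 tags over the group. With 1 to 3 tags, the fold is a pooled ratio with a 95% exact counting interval. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and Python 3.11.15.

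The groups, tests, alternatives, gene lists and naming rule were fixed before the data were examined. Named genes passed the test, had a mean of at least 50 tags over both groups and did not overlap between groups, and were not uncharacterised loci, and the 8 with the largest rise and the 8 with the largest fall were taken. Up to 4 members with the smallest adjusted p, and members that passed, were taken from each list described: target genes of p53, integrated stress response, immediate early, ribosomal protein, Pol I machinery, Pol III machinery, Pol II elongation, cholesterol synthesis, DNA replication, mitosis, aryl hydrocarbon receptor target and blood lineage genes. Further lists fixed at the same time are counted in the 96 list tests, which used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. camera compares a list with the other genes, while fry tests whether the list changed at all on the scale used. HEXIM1 and the mitochondrially encoded mRNAs, which the rule also covers, were not analysed here. Results of a few genes that the rules take are not reported. Where limma called few or no genes (BMH-21 and ML-60218), the same rule was applied to the calls of edgeR's quasi-likelihood test on recovered tags, a choice made after the data were seen. Genes named in lists of examples with a range are given by limma's estimate. Genes of the 5 h against 1 h comparisons were described from those the rule takes.

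The tests were run on simulated tags with known answers, in 3 draws under each of 2 noise models. Tags were drawn from the untreated means, the real library sizes and edgeR's estimates of spread. In each draw 200 genes were changed, as many raised as lowered. Using edgeR's spread can favour edgeR, and far more genes were called with DRB, so these rates do not carry over to the real calls. The simulation was run after the first real results had been computed, not before. Under negative binomial noise, edgeR recovered 91% of 2-fold and 99.7% of 4-fold changes for BMH-21 at 1 h (4637 genes tested), where limma recovered 50.3% and 84.3%. For BMH-21 at 5 h (4641 genes), edgeR recovered 93.7% and 99%, and limma 50% and 85.3%. For DRB at 1 h (4647 genes), edgeR recovered 73.3% and 95%, and limma 54.3% and 84.7%. For DRB at 5 h (4639 genes), edgeR recovered 38.3% and 79%, and limma 55.7% and 94%. For ML-60218 at 1 h (4641 genes), edgeR recovered 85.3% and 98%, and limma 43% and 86.3%, and at 5 h (4703 genes) edgeR recovered 89% and 99%, and limma 44.3% and 86%. In unchanged genes, limma gave an unadjusted p under 0.05 in 0.7% for BMH-21 at either time, 4.1% for DRB at 1 h, 20% for DRB at 5 h, and 1.5% and 1% for ML-60218 at 1 h and 5 h, while edgeR gave 4.5% to 5.3%. With DRB at 5 h, 65.6% of limma's calls were false (288.7 per draw), against 4.1% of edgeR's. limma pools its variance over libraries of unequal depth, and was strict for the deeper groups and lenient for the shallow DRB 5 h group. With a variance per group, it recovered 87% of 2-fold changes for BMH-21 at 1 h under the same noise. For DRB at 5 h, 31.9% of its calls were then still false, so pooling does not account for all of limma's leniency. Its 3 repairs (a variance per group, tag weights, and both) were compared on the simulated tags, and none met an acceptance rule set beforehand. The limma test was therefore kept as fixed, edgeR counts are given beside its counts, and a gene is said to have changed at 5 h of DRB only where edgeR passed too. Class sums at that time are given by limma.

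The alternatives tried were other scalings (RLE factors, all tags, 45S tags, spike-in factors, and library sizes without histone genes), other filters, a pseudocount of 1, DESeq2, the replicate number as a block, only the 4 libraries compared, all 16 libraries, each library left out in turn, class sums without their most abundant member, and summed anticodon families. Chosen after the data were seen were edgeR on recovered tags, spike-in factors for genes, a fit without the DRB libraries, limma with a variance per group, and the blocked spike-in fit.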

Results

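Newly made RNA was measured by TT-chem-seq in HAP1 cells, a near-haploid human line derived from the chronic myeloid leukaemia line KBM-7. In this assay, cells take up the uridine analogue 4-thiouridine (4-SU, 30 min at 1 mM here), and RNA that carries it is biotinylated, pulled down and sequenced. The 16 libraries formed 8 groups of 2: cells given no 4-SU, labelled untreated cells, and labelled cells given an inhibitor of a nuclear RNA polymerase for 1 h or 5 h. The inhibitors were BMH-21 (1 µM), which acts on Pol I, the enzyme that makes the 45S ribosomal precursor; DRB (100 µM), a kinase inhibitor that blocks Pol II elongation; and ML-60218 (20 µM), described as an inhibitor of Pol III, which makes tRNA and 5S rRNA. The labels call the 2 libraries of a group biological replicates without saying whether they came from separate cultures, so p-values measure the spread between these libraries only. Per library, the tags behind the tables numbered 84856292.5 and 34483720.5 without 4-SU, 46098624 and 67324519 in untreated cells, 93919776.5 and 25093324 with BMH-21 for 1 h and 66547261.5 and 50194345.5 for 5 h. They numbered 22315855.5 and 35209586 with DRB for 1 h, 18984796 and 14083584 for 5 h, 23734129.5 and 26190271 with ML-60218 for 1 h, and 42864576.5 and 37112810 for 5 h. Gene bodies of the mRNA table took 2.36% ± 0.186 of the tags in untreated cells (SD, n = 2) and 0.371% ± 0.0361 after 5 h of DRB (SD, n = 2). That left 65600 and 55845.5 mRNA tags in the DRB 5 h libraries, against 1028085.5 and 1678769.5 in untreated cells.

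The untreated cells were compared with cells given no 4-SU to measure how much unlabelled RNA the pulldown carried over. FOS, an immediate early transcription factor gene, had 0 tags without 4-SU and was at least 14.5-fold lower there, from a floor of 3 tags over the group. EGR1, of the same response, was 4.28 higher in labelled cells on the log2 scale relative to typical mRNA (SE 0.40, n = 2 per group, limma adjusted p = 1.13e-05). TXNIP, which encodes a thioredoxin-binding protein, was 4.24 higher (SE 0.41, n = 2 per group, limma adjusted p = 1.19e-05). HSP90AA1, an abundant chaperone gene, was -2.67 relative to typical mRNA (SE 0.29, n = 2 per group, limma adjusted p = 3.03e-05) but 2.92 higher on the scale of the yeast spike-in RNA. On that spike-in scale, the background without 4-SU amounted to 1.89% ± 1.18 of the untreated level for mRNA (SD, n = 2), 11.1% ± 5.29 for 45S rRNA, 6.33% ± 1.29 for 5S rRNA and 0.352% ± 0.00344 for tRNA. Of 5759 mRNA genes tested, limma called 2427, with 1525 higher and 902 lower relative to typical mRNA, and edgeR 3008 (1790 higher, 1218 lower). The spike-in scale moved the median gene from 0.35 to 4.41 and gave 4863 calls, all higher in labelled cells, while DESeq2's own size factors moved it to -0.18 and gave 1094 higher and 1849 lower.

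BMH-21 lowered 45S rRNA, the product of Pol I. After 1 h, the summed 45S regions held 22.03% ± 5.09 of the untreated level on the spike-in scale (SD, n = 2), and after 5 h 46.6% ± 1.47 (SD, n = 2). Cells given no 4-SU stood at 11.1% ± 5.29 on that scale (SD, n = 2). This unlabelled background was not subtracted, so the fall of labelled 45S rRNA can be larger than these values. Relative to mRNA the class fell by 1.96 on the log2 scale at 1 h (SE 0.15, 95% interval -2.30 to -1.63, n = 2 per group, limma adjusted p = 6.2e-05) and by 1.31 at 5 h (SE 0.15, limma adjusted p = 0.00367). All 5 annotated 45S units passed at both times. RNA45SN3 (chromosome 21, 8389035 to 8402343, GRCh38) changed most, with -2.91 at 1 h (SE 0.13, limma adjusted p = 1.04e-06) and -1.74 at 5 h (SE 0.13, limma adjusted p = 0.000227). The units are near-identical copies, so the division of tags among them is uncertain. On the spike-in scale the 1 h change of the class passed, at -2.20 (SE 0.27, limma adjusted p = 0.000546), and the 5 h change did not, at -1.10 (limma adjusted p = 0.318). That fit compares group means, although the deposited ratios pair libraries by number. Both 5 h libraries were low, at 45.6% and 47.7% of the untreated library of the same number. With only the 4 libraries compared, the 5 h change was called. Fitted without a filter on low values or with all 16 libraries, the class kept its direction relative to mRNA but lost its call at both times (limma adjusted p = 0.0642 and 0.111 at 1 h). The mRNA class stood at 85.7% ± 1.68 and 116% ± 2.83 of untreated on that scale (SD, n = 2 each), with log2 changes of -0.22 and 0.21 that did not pass (limma adjusted p = 0.887 and 0.878). The tRNA class, at 110% ± 53.5 and 171% ± 71.6 (SD, n = 2 each), did not pass either. Of 82 tRNA genes, limma called 1 and 0 at 1 h and 5 h, against 21 at an unadjusted p under 0.05 at each time, while edgeR called 22 (16 higher, 6 lower) and 13 (9 higher, 4 lower) and DESeq2 15 and 7.

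**Figure D1:**
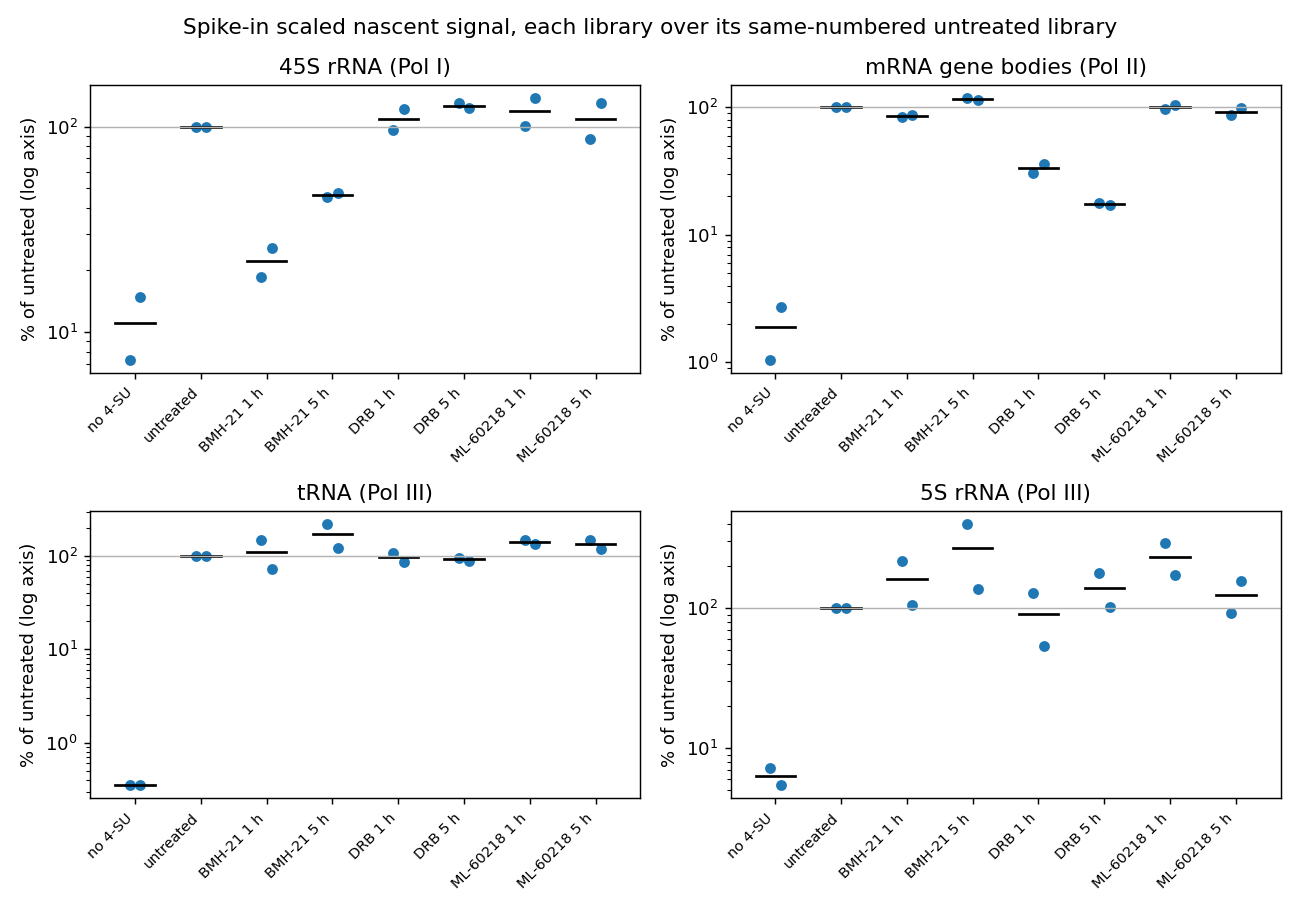
Level of mRNA, 45S rRNA, tRNA and 5S rRNA on the spike-in scale as a percentage of untreated cells (vertical log axis) in the 8 groups (horizontal axis), with 1 point per library and a line at the mean of 2. The mean of 45S rRNA was 22.03% after 1 h of BMH-21, that of mRNA was 17.3% after 5 h of DRB, and that of tRNA was 142% after 1 h of ML-60218.

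Among mRNA genes, 1 h of BMH-21 raised KRT80, a type II keratin gene (chromosome 12, 52168995 to 52192000), by 2.44 on the log2 scale (SE 0.43, n = 2 per group, edgeR adjusted p = 0.000196). ACER1, an alkaline ceramidase gene (chromosome 19, 6306141 to 6333629), rose by 1.95 (SE 0.48, n = 2 per group, edgeR adjusted p = 0.000291). CYP1B1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor (chromosome 2, 38067506 to 38076181), rose by 1.34 (SE 0.39, edgeR adjusted p = 0.00841). UBE2S, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex (chromosome 19, 55399744 to 55407777), fell by 1.21 (SE 0.25, edgeR adjusted p = 0.00105). The other named genes that rose in the edgeR test were FAM183A, NUPR1, NHLH2, TNFRSF10C and IQCJ-SCHIP1-AS1, with limma log2 changes between 1.38 and 2.21. Those that fell included the homeobox genes NKX2-3 and NKX6-1, together with ZNF469, C10orf12, CPTP and INHBB, with values between -1.30 and -0.996. None of these genes passed the limma test, which called 0 of 5522 genes at this time, against 309 at an unadjusted p under 0.05 (133 higher, 176 lower). The edgeR test on tags recovered from the deposited values called 362 (139 higher, 223 lower) and DESeq2 464 (175 higher, 289 lower).

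After 1 h of BMH-21, edgeR called 4 of the 7 tested target genes of p53, all higher, and 5 when adjusted over the list alone, whereas limma called 0 both ways. The camera test called the list higher with its preset correlation (adjusted p = 0.000808) but not with an estimated correlation (adjusted p = 0.375), and fry did not call it (adjusted p = 0.204). GADD45A, a growth-arrest gene (chromosome 1, 67685060 to 67688338), rose by 1.26 (SE 0.59, n = 2 per group, edgeR adjusted p = 0.0135). BAX, which encodes a pro-apoptotic BCL2-family protein (chromosome 19, 48954876 to 48961798), rose by 0.66 (SE 0.26, edgeR adjusted p = 0.0242), and ZMAT3 and TIGAR also rose (0.71 with SE 0.36 and 1.21 with SE 0.85, edgeR adjusted p = 0.018 and 0.0259). DNA replication genes leaned upward: edgeR called CDC6, which loads the replicative helicase, of 9 tested (0.59, SE 0.22, adjusted p = 0.0111), and 2 adjusted over the list alone, with camera at adjusted p = 0.00539 and an adjusted p = 0.199 with an estimated correlation. Among integrated stress response genes, driven by the transcription factor ATF4, edgeR called NUPR1 higher and CHAC1 and TRIB3 lower of 14 tested, and 2 higher and 3 lower adjusted over the list alone, while the camera adjusted p = 0.113 did not pass. MYC was -0.77 (SE 0.18, edgeR adjusted p = 0.00756), with KLF6 and KLF2 also lower among 16 immediate early genes. Adjusted over the list alone, edgeR called 1 of these higher and 4 lower, and the camera adjusted p = 0.267 did not pass.

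After 5 h of BMH-21, ZNF469, which encodes a zinc-finger protein (chromosome 16, 88427470 to 88440757), fell by 3.17 on the log2 scale (SE 0.46, n = 2 per group, limma adjusted p = 0.0202, edgeR adjusted p = 5.65e-07). RET, a receptor tyrosine kinase gene (chromosome 10, 43077026 to 43130351), rose by 1.19 in the edgeR test (SE 0.20, n = 2 per group, edgeR adjusted p = 3.41e-05, limma adjusted p = 0.0605). DLL4, which encodes a Notch ligand (chromosome 15, 40929392 to 40939072), rose by 1.53 (SE 0.37, edgeR adjusted p = 0.000431). XACT, a long noncoding RNA of the X chromosome (113616299 to 113938218), fell by 1.44 (SE 0.24, edgeR adjusted p = 9.83e-06, limma adjusted p = 0.0605). Higher in the edgeR test were also C9orf84, CA8, IGFBPL1, MDGA1, DACT1 and EIF5AL1, the last a near-identical copy of EIF5A whose tags are uncertain, and lower were IP6K3, SLC15A1, TNFRSF10C, ISG20, ZMAT4 and OLMALINC. ZNF469 was the only limma call of 5522, and leaving out any of the 4 libraries compared ended it. At an unadjusted p under 0.05, limma held 204 genes, while edgeR called 163 (89 higher, 74 lower) and DESeq2 223 (96 higher, 127 lower).

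Integrated stress response genes were lower as a group after 5 h of BMH-21. The edgeR test called 6 of 14, all lower, and 10 adjusted over the list alone. In limma the numbers were 0 and 7. The camera adjusted p = 6.13e-13 became an adjusted p = 0.0411 with an estimated correlation, and of the 96 list tests run, 25 passed with the preset correlation and 1, this list, with an estimated correlation. ASNS, the asparagine synthetase gene (chromosome 7, 97852117 to 97872542), fell by 0.79 (SE 0.19, n = 2 per group, edgeR adjusted p = 0.00433). The tRNA synthetase genes GARS and SARS fell by 0.76 (SE 0.22) and by 0.52 (SE 0.14), the serine synthesis genes PHGDH and PSAT1 fell by 0.60 (SE 0.17) and by 0.67 (SE 0.24), and CHAC1, which encodes a glutathione-degrading enzyme, fell by 0.90 (SE 0.40), with edgeR adjusted p between 0.00674 and 0.0432. Of 7 target genes of p53, edgeR called ZMAT3, FDXR and GADD45A lower at -0.96 (SE 0.36), -1.14 (SE 0.49) and -0.91 (SE 0.59), and 5 were lower adjusted over the list alone, with camera at adjusted p = 1.78e-05 and an adjusted p = 0.269 with an estimated correlation. Among 3 cholesterol synthesis genes, MSMO1 and MVK fell by 0.98 (SE 0.22) and by 1.04 (SE 0.24), the same 2 passing when adjusted over the list alone, with camera at adjusted p = 1.85e-05 and an adjusted p = 0.0782 with an estimated correlation. CYP1B1 was again higher at 1.66 (SE 0.39, edgeR adjusted p = 0.00383), 1 of 2 aryl hydrocarbon receptor targets, both of which passed in edgeR adjusted over the list alone.

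DRB lowered mRNA, the product of Pol II, in every library given it. On the spike-in scale the mRNA class held 33.3% ± 3.88 of the untreated level after 1 h and 17.3% ± 0.425 after 5 h (SD, n = 2 each), log2 changes of -1.59 (SE 0.21, limma adjusted p = 4.28e-06) and -2.53 (limma adjusted p = 1.19e-08). The 45S rRNA class, at 109% ± 17.8 and 127% ± 4.87, and the tRNA class, at 98.2% ± 15.4 and 92.5% ± 4.36 (SD, n = 2 each), did not pass on that scale. That fit compares group means and ignores the pairing by number. At 5 h, 45S rRNA stood at 130% and 123% of the untreated library of the same number. With only the 4 libraries compared, that 5 h change was called higher. Relative to mRNA, the classes other than mRNA rose: 45S rRNA by 1.505 and 2.45 (limma adjusted p = 2.1e-05 and 5.55e-07), tRNA by 1.36 and 1.995 (limma adjusted p = 0.000897 and 3.88e-05) and 5S rRNA by 1.12 and 2.53 (limma adjusted p = 0.0425 and 0.000252). The highest tRNA gene by this measure at 5 h was tRNA-SeC-TCA-1-1, the selenocysteine tRNA gene (chromosome 19, 45478590 to 45478687), which rose by 4.19 relative to mRNA (SE 0.27, n = 2 per group, limma adjusted p = 7.15e-07) and had 2.09 on the spike-in scale. Of 82 tRNA genes tested relative to mRNA, edgeR called 46 at 1 h and 48 at 5 h, all higher, against 46 and 58 in limma, with the same direction at 1 h and 55 higher at 5 h. The numbers in limma on the spike-in scale were 14 (7 higher, 7 lower) and 26 (14 higher, 12 lower). The 5S call at 1 h was lost without the first untreated library or the first DRB library (0.77 and 0.73), with the replicate block (limma adjusted p = 0.0553), without a filter (adjusted p = 0.0946) and with a variance per group (adjusted p = 0.137).

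The loss of mRNA after 1 h of DRB was smaller in longer genes among those with enough tags. Among genes with at least 50 tags in untreated cells, the median level on the spike-in scale was 10.6% of untreated for 594 genes under 10 kb, 16.1% for 1174 genes of 10 to 30 kb and 32.5% for 1232 genes of 30 to 100 kb. It was 51.5% for 321 genes of 100 to 200 kb and 56.8% for 120 genes over 200 kb. After 5 h the shortest and longest classes stood at 9.74% and 9.05%. How much of these 5 h levels is unlabelled background was not measured. Over all tested genes, whatever their tags, the median log2 change ran from -2.34 under 10 kb to -0.55 over 200 kb at 1 h and from -2.61 to -1.51 at 5 h, so the difference at 5 h depended on genes with few tags. Without a filter on low values, the difference over 200 kb less under 10 kb turned to -0.40 at 1 h and -1.18 at 5 h on the 45S scale. Smaller trends with span also appeared under the other inhibitors, among genes with at least 50 untreated tags. From under 10 kb to over 200 kb, medians ran from 75.7% to 94.7% (BMH-21 1 h) and from 114% to 124% (BMH-21 5 h). With ML-60218 they ran from 95.4% to 104% at 1 h and, the other way, from 105% to 83.1% at 5 h. Genes are not independent replicates, and no test was made across them.

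**Figure D2:**
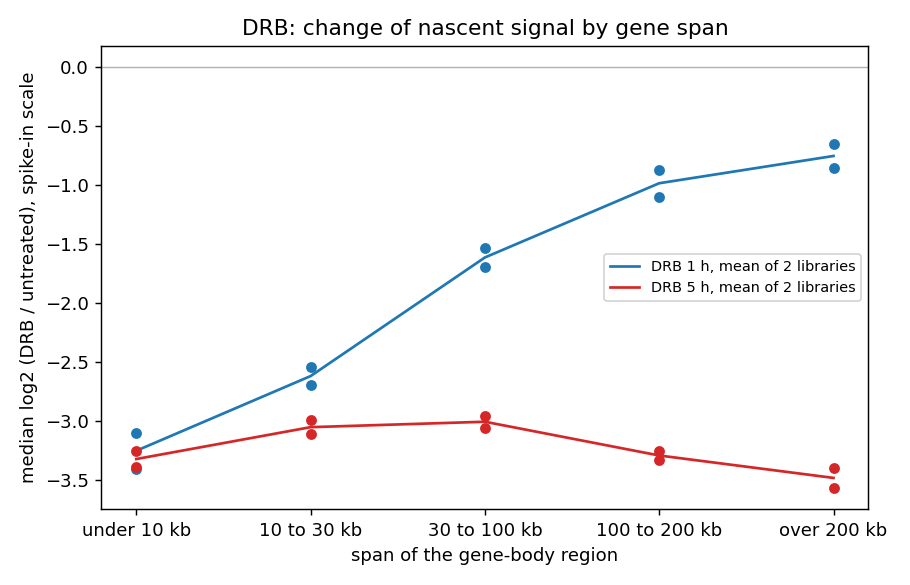
Median log2 change after DRB against untreated on the spike-in scale (vertical axis) by gene span in kb (horizontal axis), for genes of at least 50 untreated tags, with points for libraries and a line at the mean of 2. At 1 h the medians of the fitted changes ran from -3.24 under 10 kb to -0.82 over 200 kb, and at 5 h from -3.36 to -3.47.

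Among single genes after 1 h of DRB, TXNIP (chromosome 1, 145992434 to 145996600) fell by 5.93 relative to typical mRNA (SE 0.26, n = 2 per group, limma adjusted p = 3.39e-07). FOXA1, a pioneer transcription factor gene, fell by 5.12 (SE 0.49, limma adjusted p = 1.6e-05), and SPRY2, a receptor tyrosine kinase antagonist gene, was 45.8-fold lower by pooled tags (counting interval 10.6 to 639). NRBF2, ZBTB14 and SMIM10L2B, with 1 to 2 tags left, were 49.9-fold, 55.1-fold and 69.9-fold lower by pooled tags (13.7 to 413, 15.2 to 456 and 12.5 to 2770), and CDKN2AIP and FBXL22 fell by 5.502 (SE 1.26) and by 5.06 (SE 0.63). Such intervals, and the floors of 3 tags, cover counting error only. In the other direction, CCDC80, which encodes a secreted matrix protein (chromosome 3, 112596793 to 112641269), rose by 3.24 relative to typical mRNA (SE 0.24, limma adjusted p = 3.75e-06) and was 1.85 higher on the spike-in scale. TMEM74 (chromosome 8, 108783536 to 108787615) rose by 3.38 (SE 0.32, limma adjusted p = 1.42e-05), with 1.996 on the spike-in scale, and CUBN, the cubilin receptor gene (chromosome 10, 16823963 to 17129831), rose by 3.06 (SE 0.50, limma adjusted p = 0.000509), with 1.69. TNN, NUTM2G, GABRB1, SLC22A11 and MPP2 rose by 1.80 to 2.43, with spike-in values of 0.42 to 1.04. The limma test called 2455 genes, 643 higher and 1812 lower relative to typical mRNA (26.2% higher), and 2349 of them passed edgeR, which called 2892, in the same direction. The split follows the scale: on the spike-in scale 73 were higher and 3746 lower (1.9% higher), with DESeq2's size factors 1508 higher and 1473 lower (50.6% higher), and the median gene moved from -0.32 to -1.49 and 0.12.

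Among immediate early genes at 1 h of DRB, all 16 tested members passed in limma and in edgeR, over all genes and adjusted over the list alone, with a median of -1.995 relative to typical mRNA and -3.35 on the spike-in scale. All genes under 10 kb with at least 50 untreated tags had medians of -2.03 and -3.24. Most of the immediate early genes are that short, and a difference from other short genes was not tested. The camera adjusted p = 5.2e-05 became an adjusted p = 0.0989 with an estimated correlation. KLF6, a zinc-finger factor gene, fell by 3.71 (SE 0.29, n = 2 per group, limma adjusted p = 4.56e-06) and MCL1, which encodes a short-lived survival protein, by 1.27 (SE 0.14, limma adjusted p = 3.03e-05). FOS fell by 1.14 (SE 0.34, limma adjusted p = 0.017) and MYC, the growth-promoting transcription factor gene, fell by 0.67 (SE 0.18, limma adjusted p = 0.00927). Integrated stress response genes fell too, 8 of 14 in limma and 9 adjusted over the list alone, among them PPP1R15A, a phosphatase subunit gene that ends the response, which fell by 3.82 (SE 0.18, limma adjusted p = 3.4e-07). The camera adjusted p = 0.00695 became an adjusted p = 0.269 with an estimated correlation. Of 7 target genes of p53, BAX, ZMAT3, GADD45A, AEN and SESN2 fell, the same number adjusted over the list alone, without a camera call (adjusted p = 0.169) and with a fry call (adjusted p = 0.0194). Among 15 ribosomal protein genes, RPL22 and RPS14 rose relative to typical mRNA by 0.42 and 0.36 and RPL6, RPL39L, RPL14 and RPL19 fell, the same numbers adjusted over the list alone. That list's median and mean were -0.02 and -0.17 while camera pointed upward (adjusted p = 0.691), and on the spike-in scale its median was -1.41.

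After 5 h of DRB a few genes stood far above untreated cells on both scales. NIM1K, a protein kinase gene (chromosome 5, 43192224 to 43280850), rose by 5.33 relative to typical mRNA (SE 0.27, n = 2 per group, limma adjusted p = 2.74e-07, edgeR adjusted p = 6.82e-14) and was 3.23 higher on the spike-in scale. MATN2, which encodes the matrix protein matrilin (chromosome 8, 97869082 to 98036716), rose by 5.10 (SE 0.29, limma adjusted p = 3.63e-07), with 2.998 on the spike-in scale. IL12RB2, a cytokine receptor gene (chromosome 1, 67307363 to 67396900), rose by 4.63 (SE 0.34, limma adjusted p = 1.67e-06), with 2.53. CCDC80, TNN, MOBP, RBM34 and SLC22A11 also rose in both tests, by 3.04 to 3.66, with spike-in values of 0.96 to 1.56. AP5B1 and ZNF786 had 0 tags in both libraries and were at least 16.4-fold and 14.3-fold lower. FBXL22, FAM196A and ZNF200, also at 0, were at least 9.22-fold, 9.01-fold and 8.22-fold lower. KLF15, a transcription factor gene with 1 tag left, was 132-fold lower by pooled tags (23.6 to 5200), and CSF1, the macrophage growth factor gene, 74.5-fold (13.3 to 2940). The limma test called 3869 genes, 1196 higher and 2673 lower relative to typical mRNA (30.9% higher), and edgeR 3094 (1004 higher, 2090 lower), with 3060 shared in the same direction. On the spike-in scale 414 were higher and 4184 lower (9% higher), with DESeq2's size factors 1568 higher and 938 lower (62.6% higher), and the median gene moved from -0.79 to -2.54 and -0.02. On simulated tags of this comparison 65.6% of limma's calls were false against 4.1% of edgeR's, so genes are said here to have changed at 5 h of DRB only where edgeR passed as well.

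At 5 h of DRB, ribosomal protein genes were higher relative to typical mRNA but lower on the spike-in scale, where their median was -1.62. Of 15 tested, limma called 11 and edgeR 9, all higher, with the same numbers adjusted over the list alone, and the camera adjusted p = 0.000309 became an adjusted p = 0.391 with an estimated correlation. RPL22 and RPL35A, of the large subunit, rose relative to typical mRNA by 1.06 (SE 0.12, n = 2 per group, limma adjusted p = 2.1e-05) and by 1.04 (SE 0.13, limma adjusted p = 4.86e-05). Immediate early genes had parted: NR4A2, a nuclear receptor gene, fell by 2.92 (SE 0.37, limma adjusted p = 5.13e-05) and KLF6 fell by 1.67 (SE 0.29, limma adjusted p = 0.000414), while MYC rose relative to typical mRNA by 1.26 (SE 0.18, limma adjusted p = 9.71e-05; -0.85 on the spike-in scale) and EGR1 by 1.56 (SE 0.33, limma adjusted p = 0.00156; -0.53 on the spike-in scale). In all, limma called 8 of 16 lower and 2 higher and edgeR 6 and 2, the same numbers adjusted over the list alone, without a camera call (adjusted p = 0.731) but with fry lower (adjusted p = 0.00131). Target genes of p53 fell in 6 of 7 cases in both tests, and adjusted over the list alone in 7 and 6, with camera at adjusted p = 0.141 and fry at adjusted p = 0.00302. Among them, GADD45A fell by 4.19 (SE 0.59, limma adjusted p = 0.000105) and ZMAT3 by 2.65 (SE 0.36, limma adjusted p = 7.67e-05). Of the 14 integrated stress response genes edgeR called ASNS higher, at 1.02 relative to typical mRNA (SE 0.19, limma adjusted p = 0.000724; -1.06 on the spike-in scale), and 7 lower, and adjusted over the list alone 1 higher and 8 lower, without a camera call (adjusted p = 0.221) but with fry lower (adjusted p = 2.78e-05). How much of the 5 h signal of any of these genes is unlabelled background was not measured. A higher value relative to typical mRNA can therefore include such background.

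ML-60218 was compared with untreated cells for the RNA that Pol III makes, and neither the tRNA nor the 5S rRNA class passed as lower. On the spike-in scale the tRNA class stood at 142% ± 11.7 of untreated after 1 h and 134% ± 22.5 after 5 h (SD, n = 2 each), with every library above 100%. Relative to mRNA the class had log2 changes of 0.45 at 1 h (SE 0.24, 95% interval -0.08 to 0.98) and 0.51 at 5 h (95% interval -0.02 to 1.04), neither of which passed (limma adjusted p = 1 and 0.632). The 5S class had 1.11 at 1 h (95% interval 0.22 to 2.002) and 0.37 at 5 h (-0.53 to 1.26), also without passing (limma adjusted p = 1 and 0.937). The 5S direction at 5 h is uncertain. Leaving out 1 library gave values from -0.26 to 0.99, and the first library stood at 92.8% of untreated on the spike-in scale. These intervals leave out a fall of the tRNA class by more than the lower bounds given, on this scale. Of 82 tRNA genes, limma called 0 at both times. At an unadjusted p under 0.05 there were 14 at 1 h, all higher, and 22 at 5 h, 21 of them higher, while edgeR called 0 and 10, all higher, and DESeq2 2 and 9. In the edgeR test at 5 h, tRNA-Tyr-GTA-5-1, a tyrosine tRNA gene (chromosome 8, 66113366 to 66113459), rose by 1.68 (SE 0.47, n = 2 per group, edgeR adjusted p = 0.00945). The histidine tRNA gene tRNA-His-GTG-1-7 (chromosome 15, 45198605 to 45198677) rose by 1.70 (SE 0.41, edgeR adjusted p = 0.00448), and the leucine tRNA gene tRNA-Leu-CAA-1-2 (chromosome 6, 28941052 to 28941157) by 1.78 (SE 0.63, edgeR adjusted p = 0.0263). Of the tRNA genes with the highest mean tags, tRNA-Tyr-GTA-2-1 had negative values that did not pass, -0.19 at 1 h and -0.24 at 5 h relative to mRNA (limma adjusted p = 1 and 0.932; -0.14 and -0.34 on the spike-in scale). So had nm-tRNA-Tyr-GTA-chr1-142, with -0.19 and -0.12 relative to mRNA. Its name carries a prefix that sets it apart, and whether Pol III makes its RNA was not tested, so its values are no evidence on Pol III. It is part of the tRNA class, with 862.5 and 2469.5 of 8033.5 and 15961.5 tRNA tags in the untreated libraries. The 3 genes that rose also passed higher in edgeR with BMH-21, with edgeR values at 1 h and 5 h of 1.57 and 1.52 (tRNA-Tyr-GTA-5-1), 1.24 and 1.36 (tRNA-His-GTG-1-7) and 2.15 and 1.82 (tRNA-Leu-CAA-1-2). Both inhibitors were compared with the same untreated libraries, so this agreement can come from those libraries. tRNA genes of the same sequence share tags, so values of single copies are uncertain. The 45S class, at 119% ± 26.3 and 108% ± 29.8 (SD, n = 2 each), and the mRNA class, at 101% ± 4.80 and 92.2% ± 8.36, did not pass on the spike-in scale.

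After 1 h of ML-60218, TXNIP fell by 2.01 in the edgeR test (SE 0.26, n = 2 per group, edgeR adjusted p = 7.7e-07, limma adjusted p = 0.0631). It was the only mRNA gene that edgeR called of 5522. Target genes of p53 had a median of 0.73, and camera called the list higher (adjusted p = 1.85e-05; adjusted p = 0.269 with an estimated correlation), although 0 of 7 members passed over all genes in either tool, and 4 passed in edgeR adjusted over the list alone. Among them BAX had 0.73 (SE 0.26, edgeR adjusted p = 0.218). Mitosis genes had a median of -0.34, with camera at adjusted p = 1.73e-07 and an adjusted p = 0.269 with an estimated correlation. Here 0 of 13 passed over all genes, and 6 were lower in edgeR adjusted over the list alone. CENPF and CENPA, which encode centromere proteins, had -0.56 (SE 0.20) and -0.57 (SE 0.24). The limma test called 0 genes, against 146 at an unadjusted p under 0.05, and DESeq2 9 (3 higher, 6 lower).

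After 5 h of ML-60218, CHAC1 (chromosome 15, 40953148 to 40956519) rose by 1.81 in the edgeR test (SE 0.40, n = 2 per group, edgeR adjusted p = 0.000113, limma adjusted p = 0.288), and XACT fell by 1.88 (SE 0.24, edgeR adjusted p = 4.7e-06, limma adjusted p = 0.0528). CHAC1 is among the integrated stress response genes, of which edgeR called 4 of 14, all higher, and 6 adjusted over the list alone. In limma the numbers were 0 and 3. The camera adjusted p = 0.000915 became an adjusted p = 0.269 with an estimated correlation. ASNS rose by 0.68 (SE 0.19, edgeR adjusted p = 0.0153), PHGDH by 0.60 (SE 0.17, edgeR adjusted p = 0.0253) and ATF3, a stress-induced transcription factor gene, by 0.75 (SE 0.29, edgeR adjusted p = 0.0215). The same list was lower after 5 h of BMH-21, and the difference between the inhibitors was not tested.

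Of 7 Pol I machinery and ribosome biogenesis genes tested at 5 h of ML-60218, edgeR called 2 lower and limma 0, and adjusted over the list alone 4 and 2. The camera adjusted p = 1.16e-05 became an adjusted p = 0.0782 with an estimated correlation, and fry gave an adjusted p = 0.00175. DDX21, a nucleolar RNA helicase gene, fell by 0.81 (SE 0.12, edgeR adjusted p = 0.00171) and UTP20, of the small-subunit processome, fell by 0.49 (SE 0.14, edgeR adjusted p = 0.0398). Of 15 ribosomal protein genes, RPS4X fell by 0.52 at 5 h of ML-60218 (SE 0.15, edgeR adjusted p = 0.043), and 3 were lower adjusted over the list alone, with camera at adjusted p = 3.79e-06 and an adjusted p = 0.269 with an estimated correlation. Of the 7 target genes of p53, ZMAT3 fell by 0.99 (SE 0.36, edgeR adjusted p = 0.00588), and 3 were lower adjusted over the list alone, with camera at adjusted p = 0.0159 and an adjusted p = 0.492 with an estimated correlation. Other genes that rose in edgeR were DACT1, ATP2A3, GFI1, KNDC1, N4BP3, SDSL and ADSSL1, by 1.29 to 1.54 in limma's estimate. IP6K3, the exonuclease gene ISG20, the kinase gene PLK2, ZNF469, LIPI and the near-identical copies NPIPB11 and NPIPB5, whose tags are uncertain, fell. The limma test called 0 of 5522 genes, against 440 at an unadjusted p under 0.05, while edgeR called 304 (195 higher, 109 lower) and DESeq2 452 (272 higher, 180 lower).

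**Figure D3:**
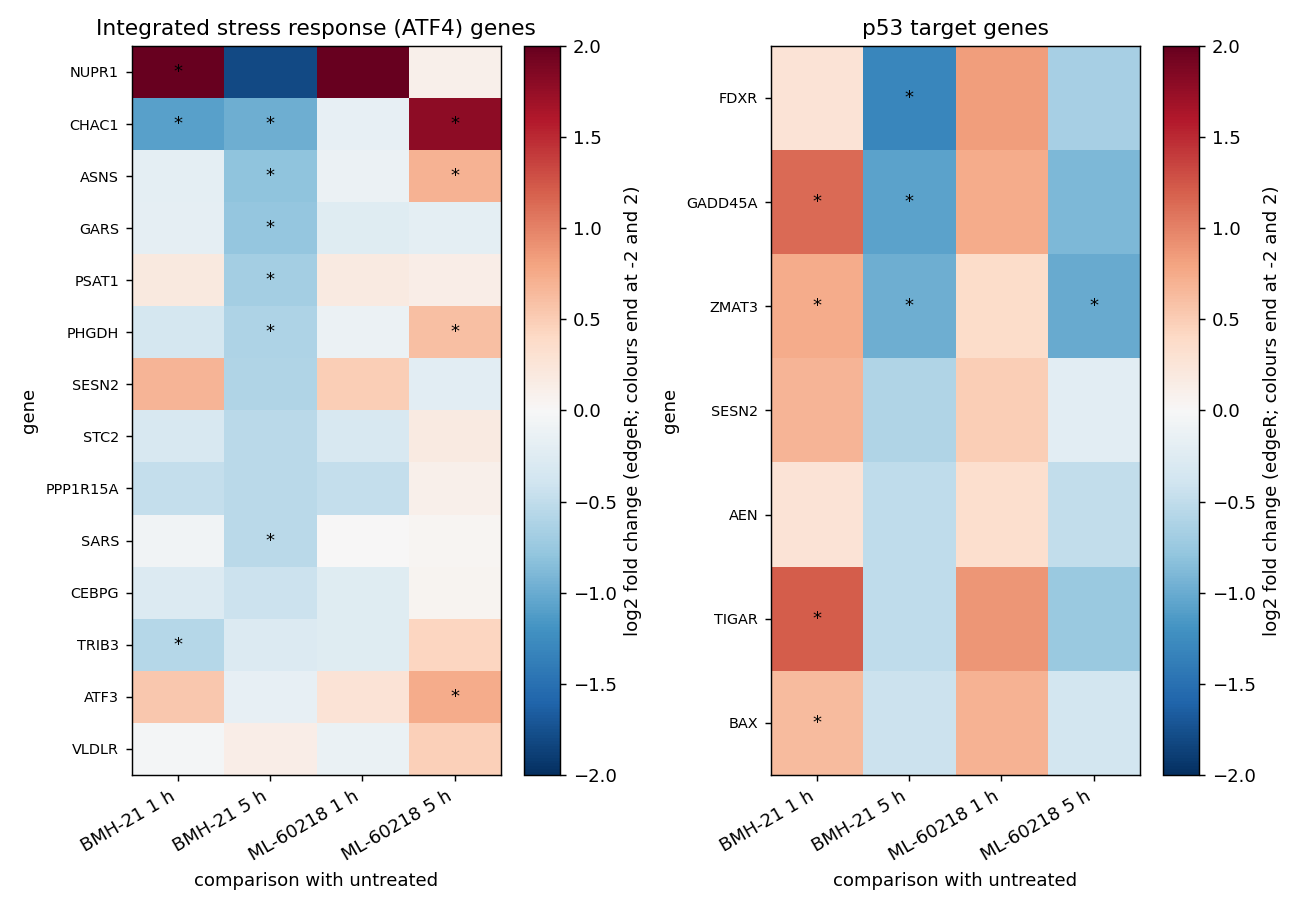
Heat map of edgeR log2 changes against untreated cells (colour, ending at ±2) for 14 integrated stress response genes and 7 target genes of p53 (vertical) in BMH-21 and ML-60218 at 1 h and 5 h (horizontal), with a star where the edgeR adjusted p passed 0.05. CHAC1 had 1.79 after 5 h of ML-60218 and -0.98 after 5 h of BMH-21.

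The 5 h and 1 h libraries of each inhibitor were compared directly for changes with time, without the untreated libraries. With BMH-21, KRT80 fell by 3.30 from 1 h to 5 h (SE 0.43, n = 2 per group, limma adjusted p = 0.0265) and NATD1 rose by 1.495 (limma adjusted p = 0.0441). The replicate block ended both calls. With ML-60218, TXNIP rose by 1.99 (limma adjusted p = 0.0415), the protocadherin gene PCDH1 by 1.72, the membrane metalloprotease gene MMP15 by 1.70, NATD1 by 1.33 and RET by 1.27. Of these, NATD1 and RET lost their calls with the replicate block. IP6K3 fell by 3.03, XACT by 1.71 and DDX21 by 0.80. With DRB, MATN2 rose by 4.28 relative to typical mRNA, IL12RB2 by 4.07 and NIM1K by 3.83, while POC1A fell by 4.24 and MAN2B2 was 84-fold lower by pooled tags (14.9 to 3330). The 45S unit RNA45SN3 rose by 1.17 relative to mRNA with BMH-21 (SE 0.13, limma adjusted p = 0.0128). Neither the 45S class nor the other units were called relative to mRNA in that comparison, and the division of tags among the units is uncertain. The limma test called 2 genes with BMH-21, 10 with ML-60218 (5 higher, 5 lower) and 3179 with DRB (1588 higher, 1591 lower). The edgeR test called 920 (515 higher, 405 lower), 616 (417 higher, 199 lower) and 2011 (963 higher, 1048 lower). The DRB split on the spike-in scale was 720 higher and 2126 lower, with DESeq2 1348 higher and 792 lower, and leaving out any of the 4 libraries compared ended the limma calls of BMH-21 and of ML-60218.

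**Figure D4:**
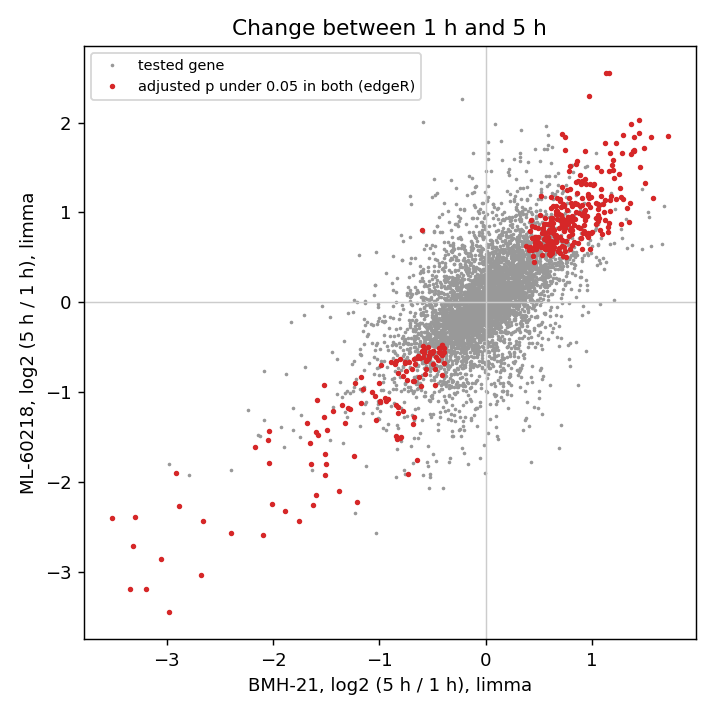
Log2 change from 1 h to 5 h by limma with BMH-21 (horizontal axis) and with ML-60218 (vertical axis), with 1 point per mRNA gene, in red where the edgeR adjusted p passed 0.05 in both. Of 5522 genes, 262 were higher and 124 lower in both.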

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

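The results in this part stood out because the 5 h and 1 h libraries of an inhibitor differed in a direct test of limma. The tests of shared changes against noise in single libraries, against gene span or level and against handling were written down before their values were computed, and the edgeR test behind the counts of shared genes was chosen after the limma result was seen.

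With BMH-21, the direct test called 2 genes, KRT80 at -3.30 (log2, 5 h over 1 h) and NATD1 at 1.495, and the 45S unit RNA45SN3 at 1.17. Neither gene passed with the replicate block. With ML-60218 it called 10, among them TXNIP at 1.99, PCDH1 at 1.72, MMP15 at 1.70, NATD1 at 1.33, RET at 1.27, IP6K3 at -3.03, XACT at -1.71 and DDX21 at -0.80.

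Changes from 1 h to 5 h were shared by BMH-21 and ML-60218, which have different targets and share no library in this comparison. Libraries of the same number deviated together between these inhibitors, by r = 0.248 at 1 h and 0.134 at 5 h, so the 2 changes may not be fully independent. Across 5522 genes the correlation was r = 0.663 (rho = 0.627; genes are not independent), against r = -0.005 and -0.015 with the DRB change. The DRB values cannot show whether the change is particular to BMH-21 and ML-60218. DRB lowered mRNA itself, and its 5 h libraries varied most between replicates (SD of log2 values 1.076). In edgeR, 262 genes rose with both, where independent lists of 515 and 417 would share 38.9, and 124 fell with both, against 14.6, among them GADD45A (-2.20 and -1.65), TNFRSF10C (-3.31 and -3.12) and IP6K3 (-2.78 and -3.20), while DACT1 (1.56 and 1.90) and LGALS1 (1.49 and 1.91) rose. Noise in single libraries is argued against, since every choice of 1 library per group kept r at 0.397 or more, and so is a trend with gene span or mean level, since r was 0.645 after its removal. A candidate explanation that stays open is time in culture or handling without any inhibitor, because 0 untreated libraries have a harvest time in the labels, and a shared response of the cells to both inhibitors cannot be told apart from it.

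With DRB, the direct test called 3179 genes. Relative to mRNA, the class changes were 0.94 for 45S rRNA, 1.41 for 5S rRNA and 0.64 for tRNA, and the units RNA45SN3, RNA45SN5, RNA45SN1, RNA45SN2 and RNA45SN4 had 0.60, 0.98, 0.77, 0.81 and 0.98. On the spike-in scale the mRNA class had -0.94. Higher at 5 h relative to typical mRNA were MATN2 (4.28), IL12RB2 (4.07), NIM1K (3.83), TXNIP (3.68), MOBP (3.36), ACY1 (3.27), RBM34 (2.69), NRBF2 (2.68), UBA3 (2.51), FAM83D (2.46), DNAH14 (2.44), ZBTB14 (2.39), FOXA1 (1.63), CUBN (1.49), TNN (1.09) and SLC22A11 (1.04). Lower were MAN2B2 (-6.44), FAM196A (-6.40), KLF15 (-6.32), ZNF786 (-5.99), CSF1 (-5.53), PDE7A (-5.37), TIGAR (-5.26), BIN1 (-5.24), SUMF1 (-4.76), POC1A (-4.24), LHX4 (-4.18), LHFPL2 (-4.17), NUTM2G (-3.59), AP5B1 (-3.58) and ZNF200 (-1.90). NRBF2, ZBTB14, FOXA1 and ZNF200 did not pass edgeR, which called 2011 genes, 1992 of them also in limma. Fitted values of genes with 3 or fewer tags in a group depend on the pseudocount and are no bounds.

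Immediate early genes that differed between the DRB times were all higher at 5 h relative to typical mRNA: EGR1 (2.78), EGR2 (2.34), KLF4 (2.32), KLF6 (2.03), MYC (1.93), CYR61 (1.77), ATF3 (1.63), KLF10 (1.54), FOS (1.23) and MCL1 (0.88). So were the ribosomal protein genes RPL19 (0.83), RPL6 (0.80), RPL27 (0.77), RPL35A (0.75), RPL11 (0.72), RPL22 (0.63), RPS4X (0.59), RPS24 (0.57), RPL14 (0.45), RPS14 (0.38) and RPS7 (0.34). Of these, EGR2, FOS, RPL14, RPS14 and RPS7 did not pass edgeR, and their change is not claimed. The mRNA class fell over the same time, so all these values are relative to it. The share of unlabelled background in these genes at 5 h was not measured. Genes under 10 kb with at least 50 untreated tags moved the same way, with medians of -2.03 at 1 h and -1.50 at 5 h relative to typical mRNA. A difference from such genes was not tested. On the spike-in scale the median of the ribosomal protein list was lower at 5 h than at 1 h of DRB.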

How the results depend on the processing

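The values under edgeR on recovered tags, spike-in factors for genes, a fit without the DRB libraries and a variance per group come from tests chosen after the data were seen. Of the values for single genes, 3884 kept direction and side of the threshold, 394 became called, 206 lost the call and 14 reversed. Of the counts, class values and other summaries, 671 stayed, 116 moved, 16 became called, 14 lost the call and 28 reversed. Where no cause is named, the cause was not tested. Depth limits the DRB 5 h libraries most, and calls of BMH-21 and ML-60218 depend on the tool, because limma's pooled variance includes the DRB libraries. mRNA counts below follow the order BMH-21 1 h (0 in the limma test), BMH-21 5 h (1), DRB 1 h (2455), DRB 5 h (3869), ML-60218 1 h (0), ML-60218 5 h (0), untreated against no 4-SU (2427), and the 5 h against 1 h tests of BMH-21 (2), DRB (3179) and ML-60218 (10), and comparisons within 1.5 times are left out.

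Scaling to all tags gave 5041, 4124, 3936 (DRB 1 h), 1 and 4 (ML-60218), 4480 (no 4-SU), 941 and 33 (5 h against 1 h, BMH-21 and ML-60218), and scaling to 45S tags gave 5151, 4272, 3972, 1, 4, 4482, 1316 and 33. These scales move the median mRNA gene, by construction, to 1.77 and 1.91 (BMH-21 1 h), 1.21 and 1.28 (BMH-21 5 h), -1.55 and -1.58 (DRB 1 h), -2.76 and -2.79 (DRB 5 h), -0.19 and -0.20 (ML-60218 1 h), -0.18 in both (ML-60218 5 h) and 2.34 and 2.37 (no 4-SU), and in the 5 h against 1 h tests to -0.57 and -0.64 (BMH-21) and -0.65 in both (DRB). Spike-in factors moved it to -0.18, 0.22, -1.49, -2.54 and -0.10 (ML-60218 5 h), and to 0.40, -0.50 and -0.13 with time, and gave 2 calls (BMH-21 1 h), 3819 (DRB 1 h), 2 (ML-60218 5 h), 4863 (no 4-SU), 82 and 51 (time, BMH-21 and ML-60218). Under all tags and 45S tags, the 5S class had 2.64 and 2.79 (BMH-21 1 h), 2.25 and 2.33 (5 h), -0.34 and -0.38 (DRB 1 h) and 0.13 and 0.0886 (DRB 5 h), and the tRNA class 2.10 and 2.24, 1.74 and 1.81, -0.11 and -0.14, and -0.41 and -0.45. The 45S class under all tags had 0.0350 and 0.0438 at DRB 1 h and 5 h. At DRB 5 h, relative to the median mRNA gene, RPS7 had -0.0812 (all tags), -0.10 (45S tags) and -0.0131 (spike-in), and RPS4X -0.0518 and -0.0698 (all and 45S tags). RLE factors gave 1 call (time, BMH-21), and AEN 0.0901 and MCL1 0.27 at DRB 5 h, and DESeq2 gave 0.0944 and 0.27. Calls at DRB 1 h on the 45S scale (3972) became 2455 with TMM and 2491 with RLE.

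DESeq2 gave 464, 223, 2506 (DRB 5 h), 9, 452, 962 and 718 (time, BMH-21 and ML-60218), and edgeR 362, 163, 1, 304, 920, 2011 (time, DRB) and 616. A variance per group gave 410, 232, 2530, 1, 554, 1070, 1361 and 545, the 4 libraries compared alone 379, 221, 1901, 3, 781, 926, 1372 and 743, and the fit without DRB libraries 222, 111, 1, 456, 670 and 1122. A pseudocount of 1 gave 1, 2, 1, 1 and 8 (time, BMH-21). No filter, and all 16 libraries, each gave 0 for BMH-21 5 h and for time with BMH-21 and ML-60218. For ML-60218 5 h, the stricter filter and the filter on unlabelled background each gave 1. tRNA calls of ML-60218 (0 and 0 in the limma test) were 2 and 9 with DESeq2, 6 and 21 with 4 libraries, and at 5 h 10 with edgeR, 16 with a variance per group and 10 without DRB libraries.

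The 45S class lost its call relative to mRNA without a filter (-1.96 and -1.31, BMH-21 1 h and 5 h) and with all 16 libraries (-1.78 and -1.15), and on the spike-in scale at 1 h without a filter (-2.20). The 5S class at DRB 1 h lost its call, at 1.12, without a filter and with a variance per group. With the 4 libraries alone, these became called: 5S at 0.81 and 1.03 (BMH-21 1 h and 5 h) and 1.08 (ML-60218 1 h), tRNA at 0.51 (ML-60218 5 h), and on the spike-in scale 45S at -1.10, 5S at 1.23 and tRNA at 0.71 (BMH-21 5 h) and 45S at 0.34 (DRB 5 h). Without the most abundant member, spike-in tRNA had 0.19 (DRB 1 h) and spike-in 45S -0.0650 (ML-60218 5 h). The difference between longest and shortest genes after DRB (1.75 at 1 h and 1.00 at 5 h, over all genes on the 45S scale) was 2.05 and 1.72 with TMM, 2.07 and 1.78 with RLE, 1.10 at 5 h with spike-in factors, -0.40 and -1.18 without a filter, 2.24 and -0.00394 with the stricter filter, 1.44 and 0.74 with a pseudocount of 1, 2.28 and 1.67 in edgeR, and 2.41 and -0.18 among genes of at least 50 untreated tags. Of 25 list calls, 1 held with an estimated correlation.

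The replicate numbers were entered as a replicate block. Samples with the same number deviated together by r above 0.1 in 5 of 21 pairs of groups (-0.032 to 0.248), and the limma test took no block. With the replicate block, calls were 1 (BMH-21 1 h), 0 (time, BMH-21) and 6 (time, ML-60218), and 5S at DRB 1 h was not called at 1.12. On the spike-in scale, whose deposited ratios pair libraries by number, the replicate block moved calls from 2 to 10 (BMH-21 1 h), 1 to 4 (BMH-21 5 h), 2 to 1 (ML-60218 5 h), 82 to 546 (time, BMH-21; 510 higher) and 51 to 80 (time, ML-60218). For time with BMH-21, the spike-in mRNA class (0.44) went from limma adjusted p = 0.231 to 0.0423 and 45S (1.10) from 0.0506 to 0.00949.

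Leaving out each library in turn ended the limma calls of BMH-21 5 h and of time with BMH-21 and ML-60218 (0 each). DRB 1 h had 1596 (without the first untreated library) to 2186 calls, and untreated against no 4-SU 1485 to 2917, with 1525 and 1485 without the first and the second untreated library. A lone library is assumed to vary like the other groups. Class values ran from -0.14 to 0.69 (tRNA, BMH-21 1 h), 0.73 to 1.51 (5S, DRB 1 h, call lost without the first untreated or the first DRB library) and -0.26 to 0.99 (5S, ML-60218 5 h). Spike-in levels ran from -0.26 to 0.34 (tRNA, BMH-21 1 h), -0.0141 to 0.23 (45S, DRB 1 h), -0.69 to 0.15 (5S, DRB 1 h), -0.26 to 0.19 (tRNA, DRB 1 h), -0.33 to 0.11 (tRNA, DRB 5 h), -0.11 to 0.14 (mRNA, ML-60218 1 h), and at ML-60218 5 h -0.29 to 0.0525 (mRNA), -0.15 to 0.33 (45S) and -0.53 to 1.06 (5S). FDXR ran from -1.08 to 0.0838 and tRNA-Tyr-GTA-2-1 from -0.63 to 0.15 at ML-60218 5 h, and nm-tRNA-Tyr-GTA-chr1-142 from -0.63 to 0.26 at 1 h and -0.54 to 0.29 at 5 h. The span difference ran from 1.29 to 1.42 at 1 h and 0.86 to 0.98 at 5 h of DRB, below the values with all libraries. The filter was applied again after each removal, with a smallest group of 1 library, so the set of genes changed too, and these ranges do not separate the library from the gene set.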

Other observations

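The tests of DRB signal in long genes against the pseudocount and against polymerases ahead of the block, and the tests of explanations for the ML-60218 result, were chosen after the result was seen.

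Single genes of further groups passed with DRB, when 2455 (1 h) and 3869 (5 h) of 5522 genes did so in limma, and camera with an estimated correlation called none of these groups. At 1 h, mitosis genes fell relative to typical mRNA in 8 of 13 cases in limma and in edgeR, the same number adjusted over the list alone, with camera at adjusted p = 0.0251, an adjusted p = 0.547 with an estimated correlation and fry at adjusted p = 0.00131. PTTG1, the securin gene, fell by 2.20 (SE 0.25, n = 2 per group, limma adjusted p = 4.78e-05) and CDK1, the mitotic kinase gene, fell by 1.95 (SE 0.32, limma adjusted p = 0.00056). Of 6 Pol II elongation genes, limma and edgeR each called 2 higher and 2 lower. CCNT1, which encodes the cyclin of the kinase that DRB blocks, fell by 2.002 (SE 0.20, limma adjusted p = 2.18e-05) and CDK7 by 1.39 (SE 0.22, limma adjusted p = 0.000481). AFF1, a super elongation complex gene, rose relative to typical mRNA by 0.93 (SE 0.16, limma adjusted p = 0.000874), with -0.46 on the spike-in scale. Adjusted over the list alone the numbers were the same, without a camera call (adjusted p = 0.803; fry adjusted p = 0.0554). At 5 h, the Pol III subunit gene POLR3E rose relative to typical mRNA by 2.49 (SE 0.21, limma adjusted p = 3.68e-06, edgeR adjusted p = 5.11e-10; 0.38 on the spike-in scale), while the other 4 Pol III machinery genes tested fell, with the same numbers adjusted over the list alone and no camera call (adjusted p = 0.499; fry adjusted p = 2.78e-05).

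SPI1, a myeloid transcription factor gene, rose after 5 h of DRB by 4.17 relative to typical mRNA (SE 0.61, n = 2 per group, limma adjusted p = 0.000135, edgeR adjusted p = 6.51e-06) and was 2.17 higher on the spike-in scale, on 8 and 5.5 tags against 2.5 and 4.5 in the untreated libraries. Of the 4 blood lineage genes tested, edgeR called SPI1 higher and RUNX1 lower, also adjusted over the list alone, and limma called ITGAM higher as well, without a camera call (adjusted p = 0.499; fry adjusted p = 0.161). After 5 h of BMH-21, the heat shock gene HSPH1 had 0.87 (SE 0.28, edgeR adjusted p = 0.00175) and the histone gene HIST1H4H had 0.79 (SE 0.18, edgeR adjusted p = 0.0141). The heat shock list as a whole was not called at 5 h (camera adjusted p = 0.267, fry adjusted p = 0.517). At 1 h of BMH-21 camera called that list lower (adjusted p = 0.0383), but not with an estimated correlation (adjusted p = 0.492).

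Neither tRNA nor 5S rRNA passed as lower with ML-60218, the Pol III inhibitor of the design. Values of the abundant gene tRNA-Tyr-GTA-2-1 were negative without passing (-0.19 and -0.24 relative to mRNA), and the 5S value at 5 h turned to -0.26 without the second ML-60218 library. Unlabelled RNA carried through the pulldown is argued against, since without 4-SU tRNA stood at 0.352% and 5S rRNA at 6.33% of untreated cells. Tags of Pol II transcripts that cover the tRNA genes are argued against too, since tRNA stood at 92.5% after 5 h of DRB, when mRNA stood at 17.3%. Whether the compound acted on Pol III in these cells at 20 µM was not tested, and a difference in tRNA processing or turnover stays open.

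The smaller loss of signal in long genes after 1 h of DRB was set against technical explanations. Unlabelled background is argued against, since genes over 200 kb without 4-SU stood at 13.8% of their level at 1 h of DRB (4.22% and 23.3% in the 2 libraries). Low values held up by the pseudocount are argued against, since the longest genes lay 2.42 above the shortest (log2) among genes with at least 50 untreated tags, but without any filter the difference was -0.40 on the 45S scale, so the result holds only for genes with enough tags. Polymerases that had left the promoter before DRB and were still moving through long genes at 1 h would leave a smaller difference at 5 h, which was -0.11 among genes with at least 50 untreated tags but 1.10 over all tested genes on the spike-in scale, against 1.79 at 1 h. That explanation therefore stays open, and it was formed and tested on the same libraries. Unlabelled background was set against the 1 h levels only, so a floor of background at 5 h could also make the difference there small.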
